A study of Mus musculus with 6 samples.

How the data were processed

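Messenger RNA was profiled in 6 libraries of 482N1, a mouse cell line derived from a lymph node metastasis of a Kras-mutant, p53-null tumour. Per the labels, the cells were kept in medium with 2 µg/mL puromycin and 10% FBS. Poly-A RNA was sequenced as paired reads of 100 bases, per the series' design text. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the mm10 genome build. Their versions and settings are not given in the sources used here.

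The processed data are 1 table of the whole series. Per the file headers, the authors deposited FPKM values, which scale fragments by transcript length and library size, with a RefSeq transcript accession and a gene symbol on each row; some accessions stood on more than 1 row. The table has 6 value columns, and each is headed by the index sequence of a library in place of a sample name. A search of all sample labels and of the design text found 0 of the 6 index sequences. No column could therefore be assigned to a sample or a group from its name. Assignment by the order of the columns, or by the values in them, was ruled out before the data were examined. Using the level of Arntl2 to find the knockdown libraries would also have fixed the outcome of the first comparison in advance. All 6 value columns were left out of the results.

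The samples were grouped from their titles. The planned comparisons were of each hairpin against the control, of both hairpins together against the control, and of the hairpins with each other, by limma on log2 values. None of them was run, and no expression value, depth, fold change or test is reported. The value columns were inspected while the file was looked at, including their totals and the correlations between them. Nothing from that inspection was used to assign a column or is reported. Every number reported from the table comes from its header and its transcript and gene identifiers, read with Python 3.11.15. Gene positions are those of GENCODE M21 on GRCm38, the assembly that mm10 names.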

Results

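The series addressed how knockdown of Arntl2 changes the transcriptome of the 482N1 line. Arntl2 encodes a bHLH-PAS transcription factor related to the circadian clock protein BMAL1. By their titles, the 6 samples form 3 groups of 2 replicates, which the series' design text calls biological. One group carried a short hairpin RNA against luciferase, which serves as a control because mouse cells have no such gene. The other groups carried 1 of 2 hairpins against Arntl2, numbered 1 and 2. The design implies a comparison of each hairpin with the luciferase control and a comparison between the hairpins.

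The expression values could not be tied to these groups. Each of the 6 columns of FPKM was named by a library index sequence, and 0 of these index sequences occurred in the sample labels or the design text. The comparisons between Arntl2 knockdown and control cells were not analysed here, and no gene is reported as higher or lower in any group. The depth of each library is not reported here for the same reason.

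The deposited table held 30982 rows, of which 27318 carried an NM (protein-coding mRNA) accession and 3664 an NR (non-coding RNA) accession. These rows covered 30479 distinct transcript accessions. Of these accessions, 268 stood on more than 1 row, which gave 503 rows beyond the first of their accession. They covered 23422 distinct gene symbols. Of these symbols, 19209 had 1 transcript accession and 4213 had more than 1.

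The targeted gene, Arntl2, was listed with 1 transcript. In GRCm38 the gene lies on the plus strand of chromosome 6, from 146796055 to 146833529. Its paralogue Arntl, which encodes BMAL1, was listed with 2 transcripts and lies on the plus strand of chromosome 7, from 113207465 to 113314126. Clock, which encodes a dimerisation partner of BMAL1, was listed with 1 transcript and lies on the minus strand of chromosome 5, from 76209868 to 76304792. Npas2, a paralogue of Clock, was listed with 1 transcript and lies on the plus strand of chromosome 1, from 39193731 to 39363236. Smoc2, which encodes a secreted matricellular protein, was listed with 1 transcript and lies on the plus strand of chromosome 17, from 14279506 to 14404790.

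All 535 genes of the 25 gene lists chosen before the data were examined were present by symbol in the table. These lists included those named core clock genes (22 members), matricellular proteins (26), chemokines and cytokines (32) and growth factors (47). Presence in the table says that a transcript was annotated, not that it was expressed.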

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

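No paired analysis was possible because the value columns match no sample. The titles number the replicates, but these numbers alone do not pair libraries across groups. The alternatives set before the data were examined were not run, since no comparison between groups was made. They concerned the pseudocount, the filter on low values, library scaling, a replicate block and the trend in the spread. They also covered a subset of groups, libraries left out in turn and the thresholds. In a check chosen after seeing the data, matching each listed gene by only the symbol written first, without its other symbols, found 528 of the 535 genes in the table.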
